A study of Mus musculus with 6 samples.

How the data were processed

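Gene expression was measured in interscapular brown and epididymal white adipose tissue of male C57BL/6 mice aged 10 to 12 weeks, kept untreated at ambient temperature, per the labels. Both tissues came from 3 mice, and each of the 6 samples was hybridised to its own Affymetrix mouse 430_2 array, a 1-colour array on which each probe set reads a transcript with several short probes. Groups were taken from the sample labels, with 3 arrays per tissue. The replicate numbers in the labels are not stated to mark the same mouse, and the arrays were therefore compared as independent samples.

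Per the file headers, each deposited array file gives 3 values per probe set: a signal intensity on a linear scale, a detection call (present, marginal or absent) and the detection p-value behind it. The software version and the scaling of the intensity are not given in the sources used here. The authors also deposited a table of signal intensities for the whole series, whose scale is linear and whose processing is not given in the sources used here. The median signal of its columns was 64.3, 62.9 and 63.8 in those named for brown and 56.7, 56.8 and 55.9 in those named for white. Its columns run opposite to the array files in tissue. The array files were used throughout, because Ucp1, Cidea and Lep run there in the directions known for these tissues. The table served only as an alternative. The directions of these genes are therefore not independent evidence. Whether the table is centred was not settled, and its direction is opposite to that of the array files.

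The files hold 45101 probe sets. After 64 control probe sets were left out, 45037 remained, of which 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Symbols were looked up through the gene identifier for 34741 probe sets, which changed 0 symbols. Probe sets with no symbol or several stayed in the test but were not named. Coordinates are not given because no genome build is named in the sources used here.

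The rule fixed in advance kept the deposited scaling unless the 2% trimmed means of the arrays differed by more than 10%. They differed by more, so the log2 signals were quantile-normalised between arrays. The 1 signal of exactly 0 was set to 0.1 before taking log2. Probe sets called present on at least 3 of the 6 arrays were tested, 19819 in all. Differences (brown minus white) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal), with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene or probe set past that threshold is described as higher in one tissue. For 10264 genes, 1 probe set per gene was used, the one with the highest mean log2 signal over all 6 arrays, and the adjustment was repeated over these genes. Tissue means and SDs are of the normalised signals on the linear scale, and log2 differences are differences of mean log2 signals. Where a probe set was called absent on all 3 arrays of the dimmer tissue, the ratio is given as a lower bound. The bound sets the mean log2 signal of the brighter tissue against, on each dimmer array, the higher of the lowest signal called present and the probe set's own signal. These are ratios of geometric means over the arrays, and can lie above the ratio of the printed arithmetic means where the dimmer arrays spread. With such members at their bounds, the median of each list was unchanged.

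Gene lists (29) for adipocyte types, metabolic pathways, regulator families and other cell types were fixed before the data were examined, as were the tests and the rule for naming genes. Lists with at least 3 tested members (27) were tested with camera from limma, two-sided, at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Members were counted over all genes tested and adjusted over the list alone. The lists came from general knowledge of these tissues, so the direction of the brown and white adipocyte lists is not independent evidence. The text names the 12 genes with the largest difference in each direction among genes past the threshold whose arrays did not overlap and which were present on all 3 arrays of the higher tissue. That order rests on log2 differences, has no meaning among genes at background in the dimmer tissue, and is not the order of the bounds. It also names up to 4 called members of each list in the direction of most of its calls, up to 2 in the other direction and up to 2 members not called with the highest signal, together with Ucp1, Prdm16, Cidea, Ppargc1a, Lep, Adipoq, Fabp4, Pparg and Actb. Gapdh is not reported because its probe sets are assigned to several genes.

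The fit and the adjustment were tested on simulated data with 19819 probe sets, for brown against white with 3 arrays each. The values were drawn as already normalised and filtered, so normalisation and the detection filter were not tested. Only 50 probe sets were changed at each size, far fewer than differed in the measured data. Simulated log2 changes of 0.5 were recovered in 30% of cases, of 1 in 68%, of 2 in 90% and of 3 in 94%, with 2 false calls. The number of arrays limits the precision. Array-level measures were compared with an exact two-sided permutation test, which cannot give a p below 0.1 with 3 arrays against 3. Alternatives covered the scaling, an added constant of 16 or 64 signal units, the detection filter, probe sets prone to cross-hybridisation, the variance trend, a replicate block, the choice of probe set, the series table and each array left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.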

Results

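The arrays compare interscapular brown adipose tissue, which burns fat to produce heat, with epididymal white adipose tissue, which stores it, in order to find genes selective for either. Each tissue was represented by 3 arrays of separate samples. All brown tissue was interscapular and all white tissue epididymal, so the type of fat and its site in the body cannot be told apart. Probe sets called present made up 36.6% ± 0.947 (SD, n = 3) of each brown array and 45.4% ± 0.285 (SD, n = 3) of each white array (exact permutation p = 0.1, the smallest p possible with 3 against 3). The median deposited signal was 38.5 ± 0.902 in brown and 52.4 ± 0.231 in white (SD, n = 3), while the spike-in hybridisation controls had mean log2 signals of 10.64 and 10.63. The actin 3'/5' signal ratio, a measure of RNA integrity, was 1.67 ± 0.493 in brown and 1.44 ± 0.276 in white (SD, n = 3; exact permutation p = 0.6), with the highest value, 2.24, on brown replicate 2. Normalised log2 signals correlated at 0.959 to 0.965 among brown arrays, 0.981 to 0.983 among white arrays and 0.808 to 0.818 between tissues. All signals below are quantile-normalised, given as mean ± SD with n = 3 per tissue, and all differences are brown minus white. Folds are ratios of geometric means over the 3 arrays, not of the arithmetic means printed beside them, and "at least" marks a gene called absent on all arrays of the dimmer tissue.

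Ucp1, the uncoupling protein that lets brown fat mitochondria release energy as heat, had a signal of 12940 ± 267 in brown and 26.1 ± 31.7 in white (62.5, 4.58 and 11.2 on the single arrays, all called absent). The ratio of its geometric means was at least 877-fold towards brown (adjusted p = 1.5e-06). Leptin (Lep), the hormone that reports fat stores, had a signal of 54.2 ± 19.2 in brown and 1743 ± 16.5 in white, a log2 difference of -5.08 (adjusted p = 6.08e-08). Of 10264 genes tested, 2895 were higher in brown and 3361 were higher in white, 61% together. Of 19819 probe sets, 4885 were higher in brown and 5924 in white, and 1987 and 2666 of these differed at least 2-fold. The latter counts were 1210 and 1379 with 64 signal units added, and 1491 and 1241 among probe sets present on all 6 arrays, where the larger side turned. The larger side changed when any white array was left out, with 4469 higher in brown and 4259 in white without white replicate 1, 4432 and 4194 without white replicate 2, and 4394 and 4168 without white replicate 3. The number at least 2-fold higher in white was then 1698, 1713 and 1693, and the probe sets tested fell to 17277, 17322 and 17317. The filter still asked for 3 present calls, so probe sets present on the white arrays alone were no longer tested. The arrays of the tissues did not overlap for 62.4% of the tested probe sets, where chance gives 10%. The split also depended on the scaling: 2535 probe sets were higher in brown and 10785 in white with the deposited scaling, 2278 and 10340 with scaling to the spike-in controls, and 5946 and 4889 with each array centred on its median. The median log2 difference of all tested probe sets was -0.06 after quantile normalisation, -0.53 with the deposited scaling, -0.54 with spike-in scaling and 0.06 with median centring, and differences are relative to that level.

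**Figure D1:**
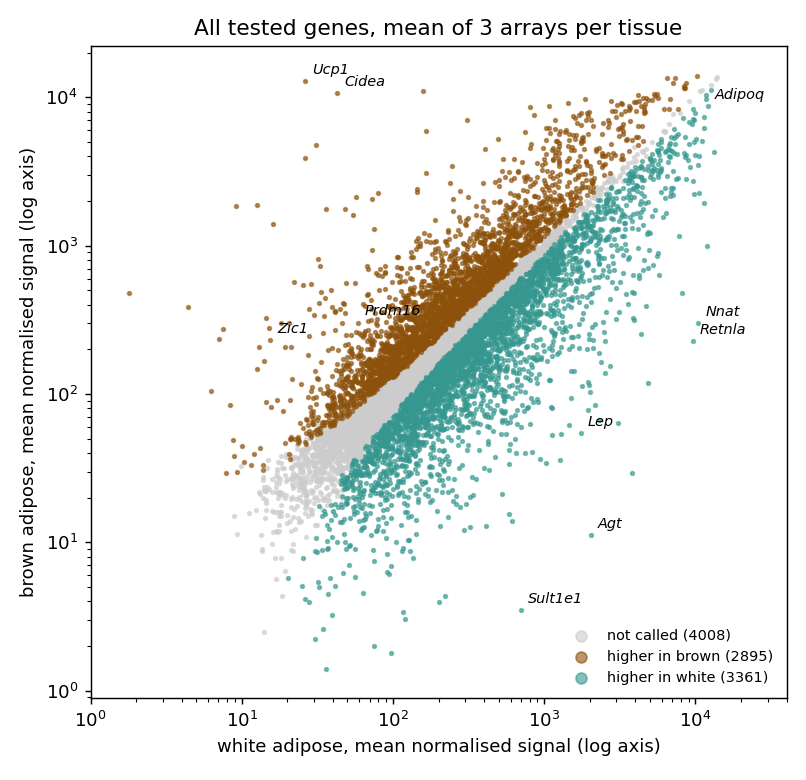
Mean quantile-normalised signal of each tested gene in white (x, log axis) and brown (y, log axis) adipose tissue, 3 arrays each. Points are coloured by whether limma called the gene higher in brown (2895), higher in white (3361) or neither, and Ucp1 and Cidea lie far above the diagonal while Lep, Agt and Sult1e1 lie far below it.

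The brown adipocyte list had 27 tested members, of which 26 were higher in brown and 1 in white, with a median log2 difference of 4.45 (camera adjusted p = 1.55e-15). With an estimated correlation the camera adjusted p of this list was 0.0226. Cidea, a lipid droplet protein, had a signal of 10700 ± 169 in brown and 42.6 ± 27.2 in white (log2 difference 8.28). The fatty acid transporter Slc27a2 was at least 183-fold higher in brown and the proton channel Otop1 at least 201-fold. Fabp3, a fatty acid binding protein of heart and muscle, reached 3872 ± 220 in brown against a mean of 26.3 in white, and the potassium channel gene Kcnk3 was at least 57.5-fold higher. Prdm16, a transcriptional regulator of brown adipocytes, was higher in brown at 302 ± 13.8 against 58.5 ± 9.48 (log2 difference 2.38), and the coactivator Ppargc1a by a log2 difference of 2.50. Epsti1 was the 1 member higher in white, at a log2 difference of -0.53 (adjusted p = 0.0381), a call lost without brown replicate 1 (0.0973), brown replicate 3 (0.116), white replicate 1 (0.12) or white replicate 3 (0.105). Outside the list, genes higher in brown included Kng1, which encodes kininogen (480 ± 32.6 against 1.80 ± 0.550, at least 110-fold), Cpn2 (at least 80.2-fold), Aspg (at least 98.6-fold) and Adtrp (log2 difference 5.26).

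All 22 tested members of the white adipocyte list were higher in white, with a median log2 difference of -3.34 (camera adjusted p = 1.62e-12). Agt, which encodes angiotensinogen, was at least 174-fold higher in white (2030 ± 51.0 against 11.2 ± 3.65 in brown). Sncg, gamma-synuclein, had a log2 difference of -7.01, Nnat of -5.12 and the homeobox gene Hoxc8 of -5.10. Genes higher in white also included the estrogen sulfotransferase Sult1e1 (at least 90.2-fold), Olfml1 (at least 26.2-fold), Olfm1 (at least 28.5-fold), Adgrg2 (at least 46.9-fold), Tnfrsf11b, which encodes osteoprotegerin (at least 4.69-fold), Plagl1 (-5.58) and the resistin-like gene Retnla (9606 ± 183 against 228 ± 79.1 in brown). Ear3 was at least 15.3-fold higher in white, but its probe set is of a kind shared within its gene family and the identity of the transcript is uncertain.

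**Figure D2:**
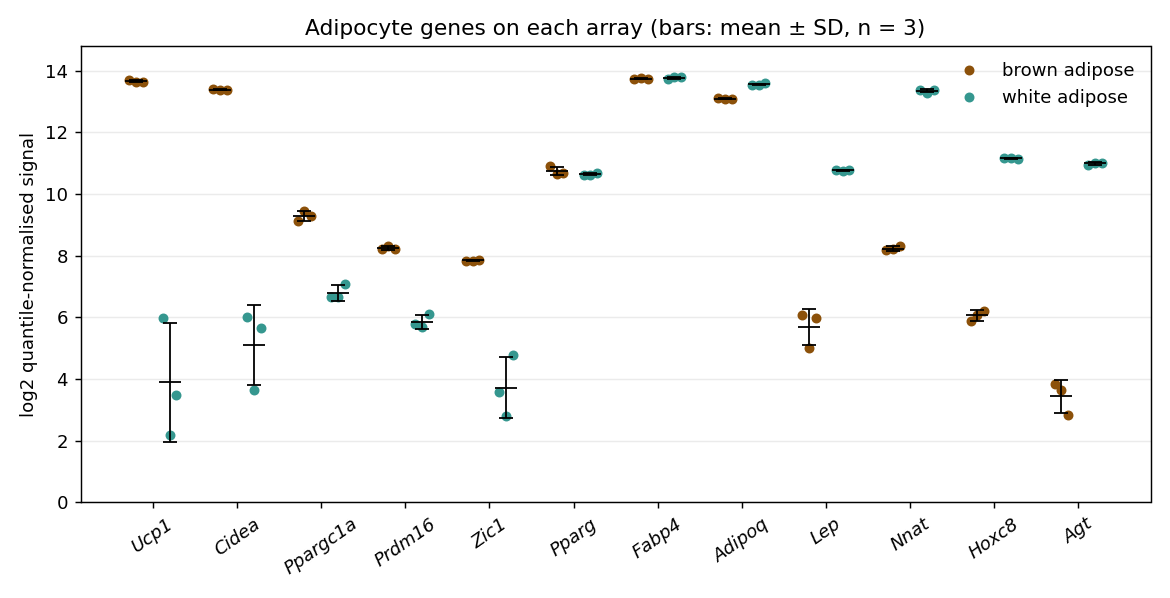
Log2 quantile-normalised signal (y) of 12 adipocyte genes (x) on each of 3 brown and 3 white arrays, with bars for mean ± SD of the log2 values. Ucp1, Cidea, Ppargc1a, Prdm16 and Zic1 are higher in brown, Lep, Nnat, Hoxc8 and Agt are higher in white, and Pparg and Fabp4 overlap between tissues.

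Genes shared by both adipocyte types went both ways. Of 24 tested members, 5 were higher in brown, 12 in white and 7 were not called (camera adjusted p = 0.148; median -0.19), and with median centring the list was called higher in brown (median 0.32, adjusted p = 0.0452). The fatty acid binding protein Fabp4 had signals of 13690 ± 76.8 and 13980 ± 294 (log2 difference -0.03, adjusted p = 0.453), near the brightest signals of the arrays. The mean over its probe sets was higher in white (-0.83), and with median centring Fabp4 was called higher in brown (0.49). Pparg, the nuclear receptor that drives fat cell formation, gave 1724 ± 172 and 1593 ± 29.5 (0.11, adjusted p = 0.236; 0.46 and called with median centring). Adiponectin (Adipoq) was higher in white by a log2 difference of -0.47, which became 0.17 with median centring. Plin4 (-1.83), Cidec (-1.42) and Cebpd (-2.11) were higher in white, while Gpd1 (2.16) and Cebpb (2.02) were higher in brown. The control gene Actb had a difference of -0.66 (adjusted p = 0.000594), and of -0.01 with median centring.

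Mitochondrial genes were higher in brown almost throughout. In the oxidative phosphorylation list, 70 of 73 tested members were higher in brown, 2 in white and 1 was not called (median 1.44; camera adjusted p = 1.32e-29). The cytochrome c oxidase subunits Cox7a1 (4746 ± 435 against 31.2 ± 5.43) and Cox8b (11010 ± 826 against 159 ± 15.3) differed most, and Ndufs1 of complex I had a difference of 2.60. The exceptions were Atp5g1 and Atp5g3, which encode the c subunit of ATP synthase: Atp5g1 was at least 12.8-fold higher in white, and Atp5g3 had 5417 ± 26.3 against 8578 ± 58.0 (-0.66; 0.02 with median centring). All 20 tested genes of the tricarboxylic acid cycle were higher in brown (median 1.99; adjusted p = 2.03e-15), among them Suclg1 (2.60), Sdhd (2.39) and Dlst (2.35). In the mitochondrial ribosome list, 73 of 76 were higher in brown and 1 in white (median 1.13; adjusted p = 4.78e-22), or 74 and 1 adjusted over the list alone, with Mrps36 at 2.73 and Mrpl34 at 2.41. Mrps6 was higher in white at -0.44. This call was lost with median centring (-0.16) and with probe sets prone to cross-hybridisation left out (-0.19, limma adjusted p = 0.137). With an estimated correlation the camera adjusted p was 0.00323 for oxidative phosphorylation, 0.0296 for the tricarboxylic acid cycle and 0.00796 for the mitochondrial ribosome.

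Of 26 fatty acid oxidation genes, 25 were higher in brown and 1 in white (median 1.74; camera adjusted p = 6.34e-14). Acaa2 (8625 ± 203 against 809 ± 24.5), Acadvl (3.16) and Etfdh (2.84) were higher in brown, and Cpt1a, a form of carnitine palmitoyltransferase found in liver, was higher in white (172 ± 28.3 in brown against 739 ± 81.4). Glycolysis genes were higher in brown in 12 of 14 cases (median 1.02; adjusted p = 1.09e-05), including Ldhb (3.42), Pfkl (2.55) and Pkm (2.09), and Pfkfb3 was higher in white (-0.35; 0.24 with median centring). The lipogenesis and triglyceride list had 12 members higher in brown, 5 in white and 6 not called, or 12 and 6 adjusted over the list alone (median 0.52; camera adjusted p = 0.00962, and adjusted p = 0.147 with an estimated correlation). With median centring 17 members of this list were higher in brown and 4 in white (median 1.13). The elongases Elovl3 (4.45) and Elovl6 (3.47) and the carboxylase Acacb (2.52) were higher in brown. The acyltransferases of triglyceride synthesis Gpat3 (-3.10) and Mogat1 (-1.76) were higher in white. Scd1 was not called at -0.06, and another of its probe sets was called the other way. The peroxisome list had 16 members higher in brown, 4 in white and 5 not called (median 0.70; adjusted p = 0.000237), or 14 and 7 with the deposited scaling, with Abcd3 at 1.93 and Crat at 1.70 and the transporter Abcd2 at -3.28. Pmp22, also in that list and higher in white (-1.92), is a peripheral myelin protein.

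Cytosolic ribosomal protein genes were higher in white in 32 of 41 cases and in brown in 2, or 32 and 3 adjusted over the list alone (median -0.45; camera adjusted p = 1.28e-06, and adjusted p = 0.0525 with an estimated correlation). Rps4x had 3025 ± 127 in brown against 5675 ± 27.5 in white, and Rpl6 2826 ± 26.8 against 5251 ± 199. The direction of this list turned with median centring, where 19 members were higher in brown and 8 in white (median 0.12, adjusted p = 0.231), and its call was lost with spike-in scaling (adjusted p = 0.0614). Of 13 cell cycle genes, 1 was higher in brown, 4 in white and 8 were not called (1 and 3 adjusted over the list alone; median -0.31; adjusted p = 0.406), with Tpx2 at 0.92. With deposited and spike-in scaling 8 cell cycle genes were higher in white (medians -0.77 and -0.78). Without white replicate 2 or white replicate 3 there were 2, of 10 still tested.

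Among 28 nuclear receptors tested, 12 were higher in brown, 7 in white and 9 were not called, or 13 and 7 adjusted over the list alone (median 0.15; camera adjusted p = 0.0827). With the deposited scaling camera called the list higher in brown (adjusted p = 0.0247) although its median was -0.25 and 12 members were higher in white. Ppara, a regulator of fatty acid oxidation, had 2056 ± 125 in brown against 72.6 ± 25.1 in white (4.87), where it was called marginal on 1 array and absent on the others. Nr4a1 had 3077 ± 396 against 166 ± 10.5 (4.20), Nr4a3 was at least 16.1-fold and Esrrg at least 13.8-fold higher in brown, and Rxra (-1.38) and Nr2f1 (-1.38) were higher in white. Homeobox and patterning genes went both ways, with 4 higher in brown, 10 in white and 8 not called of 22 (6 and 10 adjusted over the list alone; median -0.16; adjusted p = 0.44). The list's median was -0.55 without brown replicate 1, -0.05 without white replicate 3 and -0.62 with the deposited scaling. Zic1 was at least 17.5-fold and Hoxa4 2.42 on the log2 scale higher in brown, while Tcf21 was at least 12.9-fold higher in white and Gata6 had -2.27. Of 8 Prdm and Fog family genes, Prdm16 was higher in brown, Zfpm2 was higher in white (-2.13) and 6 were not called; the median was -0.09 and the mean -0.06, while camera's direction was towards brown (adjusted p = 0.968), and 5 were higher in white with the deposited scaling.

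**Figure D3:**
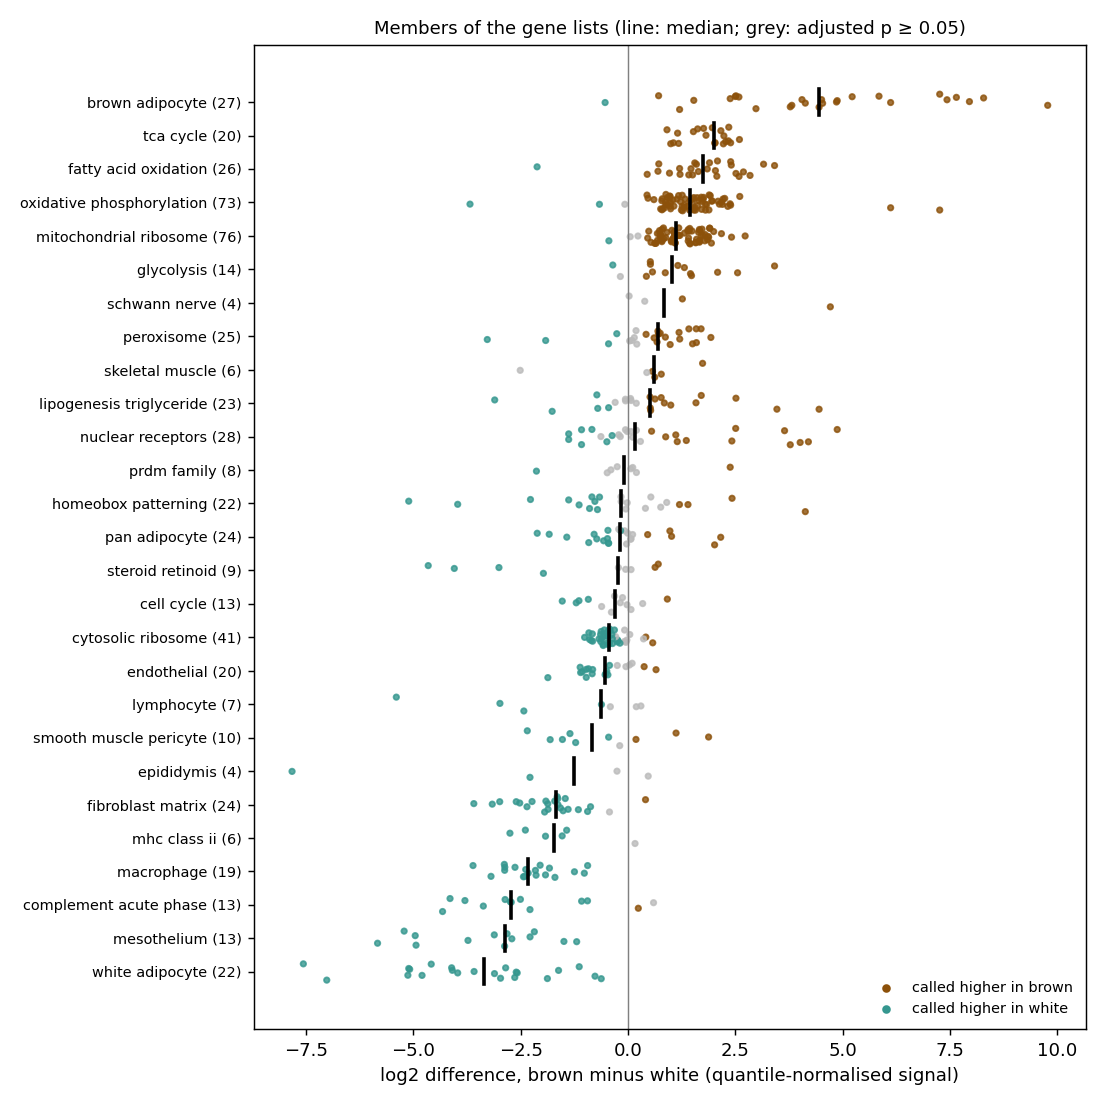
Log2 difference (x, brown minus white, quantile-normalised) of each tested member of the gene lists with at least 3 tested members (y, number tested in brackets), with a black line at each median. Brown and green points were called higher in brown and in white and grey points were not called; the medians run from 4.45 for the brown adipocyte list to -3.34 for the white adipocyte list, and that of the cytosolic ribosome list (-0.45) turned to 0.12 with median centring.

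Markers of other cell types also differed between the tissues. All 19 tested macrophage genes were higher in white (median -2.32; camera adjusted p = 1.84e-10), including C1qc (188 ± 7.77 in brown against 2294 ± 225) and Lyz2 (630 ± 30.6 against 5733 ± 47.6). All 13 mesothelial genes were higher in white (median -2.87; adjusted p = 9.06e-06), with Msln, which encodes mesothelin, at least 12.5-fold and Slpi at least 37.0-fold higher. Without any 1 white array only 3 mesothelial genes were still tested, since the filter kept asking for 3 present calls, and these 3 were higher in white (adjusted p from 0.0232 to 0.0272). Of 24 fibroblast and matrix genes, 22 were higher in white and 1 in brown, or 23 and 1 adjusted over the list alone (median -1.68; adjusted p = 9.3e-12). Fibronectin (Fn1) had 391 ± 9.36 in brown against 4699 ± 172 in white, and Postn was higher in brown (0.41), a call lost with the deposited scaling (0.09). Endothelial genes were higher in white in 14 of 20 cases and in brown in 2, or 15 and 2 adjusted over the list alone (median -0.52; adjusted p = 0.00326, and adjusted p = 0.0525 with an estimated correlation). Vwf had a difference of -1.86 and Cdh5 of -1.06. With deposited and spike-in scaling 18 endothelial genes were higher in white and 0 in brown (medians -1.04 and -1.05). Flt1 was higher in brown at 0.38 but had -0.12 with the deposited scaling. Of 6 class II antigen presentation genes, 5 were higher in white (median -1.72; adjusted p = 0.00158, and adjusted p = 0.0674 with an estimated correlation), with Cd74 at -2.75.

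The immunoglobulin gene Ighm was at least 42.0-fold higher in white. Of 7 lymphocyte genes 4 were higher in white and 3 not called (median -0.62, camera adjusted p = 0.0827). Without white replicate 1, 2 or 3 there were 6 tested, with medians of -1.537, -1.545 and -1.463. Smooth muscle and pericyte genes had 3 higher in brown, 6 in white and 1 not called (median -0.83, camera adjusted p = 0.179). Acta2 had a difference of -1.52, and Des was at least 3.68-fold higher in brown. Without the detection filter 8 of the list were higher in white and 3 in brown, and the list was called (median -0.92, camera adjusted p = 0.0266). The Schwann cell list had 2 of 4 members higher in brown, S100b (4.71) and Mbp (1.27), and 2 not called (median 0.83; adjusted p = 0.0827, and 0.0413 with the deposited scaling). Of 25 skeletal muscle genes, 6 were tested and 4 were higher in brown (median 0.60; adjusted p = 0.179). Myl1 was 1011 ± 149 against 306 ± 75.1, while Casq1 (0.78), Ttn (0.62) and Eno3 (0.57) each lost their call without some single array, Casq1 with an adjusted p of up to 0.132, Ttn of up to 0.107 and Eno3 of up to 0.155. With the deposited scaling 1 muscle gene was higher in brown and 1 in white. Acta1 had 81.6 ± 72.7 in brown and a mean of 180 in white (-2.51, adjusted p = 0.113), and was called without brown replicate 2 (-3.63, adjusted p = 0.0258), with the deposited scaling (-2.98, 0.0472), with spike-in scaling (-2.99, 0.0135) and with 64 signal units added (-0.89, 0.0338). Of 4 epididymis genes tested, Sult1e1 and Lcn2 were higher in white and 2 were not called (median -1.27; adjusted p = 0.343). The list's median was -2.51 without brown replicate 1, with 3 genes tested, and -0.89 without brown replicate 3. With deposited and spike-in scaling 3 of its genes were higher in white. The arrays of the tissues overlapped for Lcn2, and its call was lost without the variance trend (adjusted p = 0.0732). Too few myogenic regulators and erythroid genes, 2 each, were measured for a test of the list: Mef2c was higher in white (-0.84), and Eya1, Alas2 and Slc4a1 were not called.

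Complement and acute phase genes were higher in white in 11 of 13 cases and in brown in 1 (median -2.72; camera adjusted p = 0.000135). Without white replicate 1, 2 or 3 there were 8 tested and 6 higher in white, with medians of -1.81, -1.79 and -1.84. Serpina3n had 103 ± 25.4 in brown against 2015 ± 81.3 in white, and C2 was at least 17.7-fold and Lbp at least 13.9-fold higher in white. Orm1 was higher in brown at 0.24, a call lost without brown replicate 2 (adjusted p = 0.115), brown replicate 3 (0.0638), white replicate 2 (0.117) or white replicate 3 (0.0935), and its difference was -0.10 with the deposited scaling. Of 9 steroid and retinoid genes, 4 were higher in white, 2 in brown and 3 were not called (median -0.22, camera adjusted p = 0.148). Without any 1 white array 7 were still tested and 2 were higher in white. The retinaldehyde dehydrogenases Aldh1a1 (at least 25.1-fold) and Aldh1a2 (at least 16.5-fold) and the retinol binding protein Rbp4 (-1.97) were higher in white, and Hsd17b12 was higher in brown (0.71). With an estimated correlation 12 of the 16 list calls held. Their camera adjusted p then ran from 0.00323 (oxidative phosphorylation) to 0.0296 (tricarboxylic acid cycle, peroxisome and complement). The far smaller camera p-values above were obtained with the preset correlation of 0.01. The estimated correlation lay below that for some lists, such as oxidative phosphorylation (0.001) and macrophage (-0.026). It lay above it for others, such as the tricarboxylic acid cycle (0.159). A higher correlation between members therefore cannot account for all of the larger p-values. In 21 of the 29 lists the counts adjusted over the list alone equalled those over all genes.

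By detection calls alone, 181 probe sets were present on all brown arrays and absent on all white arrays, and 1828 the reverse (34 and 308 with stricter detection p-values). The share of probe sets called present was also lower on the brown arrays, as given above. How far that share sets these counts was not tested. The deposited series table placed the tissues the other way round: Ucp1 averaged 13240 ± 48.4 in the columns named for white and 55.2 ± 36.1 in those named for brown (SD, n = 3), and Lep averaged 114 and 5060. In the array files Ucp1 averaged 12540 ± 287 in brown and 30.6 ± 37.5 in white before normalisation.

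**Figure D4:**
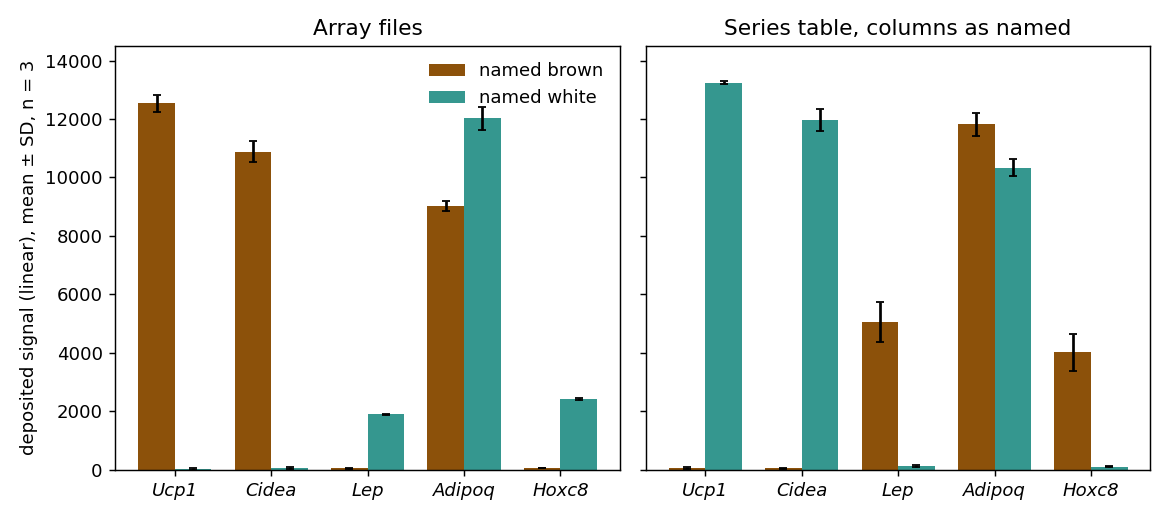
Deposited signal (y, linear, mean ± SD, n = 3) of 5 genes (x) in the array files and in the series table, by the tissue each array or column is named for. Ucp1 and Cidea are bright on the brown arrays but in the table's columns named for white (13240 and 11970), and Lep and Hoxc8 show the reverse.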

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

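Both tests of this part were chosen after the direction of the series table had been seen. Ucp1 drew attention because the deposited series table, which no comparison above uses, gives it a mean signal of 13240 in the columns named for white adipose tissue, where the array files named for white average 30.6. Over all 182 named genes, 170 had the opposite sign in the table. One explanation is that the table's columns of one tissue hold the values of the other: for 6 of 6 array files, the deviations from the tissue mean correlated best with the column of the same replicate number in the other tissue (0.339 to 0.393, against at most 0.089 for any other column). Had the array files carried the wrong tissue, the brown adipocyte list would run towards white on them. Its median log2 difference there was 4.45 towards brown, with Ucp1, Cidea and Lep called in the directions these tissues are known for. The array files had been chosen for the directions of Ucp1, Cidea and Lep, and the list holds Ucp1 and Cidea. Neither these genes nor the list is therefore independent evidence. How the exchange arose stays open, and no biological explanation was tested, since both sources are named for the same samples.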

How the results depend on the processing

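Deposited scaling, spike-in scaling and the sign-turned table were added after the data were examined; the other alternatives were planned. Of 144 named genes called, 121 kept direction and call under every alternative that tested them, the table as named aside. The count of probe sets higher at least 2-fold was 2589 with 64 signal units added, which shrinks low signals, and 2732 with probe sets present on all 6 arrays, where 13144 were tested. Probe sets detected in 1 tissue only numbered 342 with stricter detection p-values. With the series table as named, 170 of 182 named genes had the opposite sign, and 13274 probe sets, 4757 at least 2-fold, 7259 genes and 16 lists were called, with log2 differences of -8.29 for Ucp1, -8.18 for Cidea and 5.10 for Lep. With its sign turned, the correlation with the array files was 0.874 and Flt1 had -0.29. Median centring gave Atp5g3 0.02, Pfkfb3 0.24, Adipoq 0.17 and the cytosolic ribosome list a median of 0.12. Flt1 had -0.12 and -0.13, and Orm1 -0.10 and -0.11, with deposited and spike-in scaling. The cause was not tested.

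Leaving out 1 array at a time gave 8562 to 10408 probe sets, 3671 to 4535 at least 2-fold, 5159 to 5979 genes, 16 to 16 lists and 2379 to 2522 probe sets detected in 1 tissue. The last count then asks for calls on fewer arrays, so it cannot fall below the 2009 of all 6 arrays and does not measure stability. Among named genes still tested in these fits, 8 lost their call: Casq1, Eno3, Epsti1, Orm1 and Ttn as given above, and Cd2, Mcm2 and Star with adjusted p of up to 0.125, 0.072 and 0.109. Without brown replicate 2, whose actin ratio was highest, 10408 probe sets were called, 4543 higher in brown and 5865 in white. With the replicate block, 10468 probe sets, 4669 at least 2-fold, 6056 genes and 16 lists were called, and Acta1 was called at -2.51 (adjusted p = 0.0466). Same-numbered arrays did not deviate together (correlations 0.017, -0.014 and -0.046). With so few arrays this cannot show whether equal numbers mark the same mouse. The samples were compared unpaired because the labels do not state it. Quantile normalisation, planned as an alternative, became the reported setting by the rule fixed in advance, and a batch block was not run because the files give no batch holding over 1 array. Signals near background limit folds to bounds, and Ucp1 and Fabp4 lie close to the brightest signals.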

Other observations

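The lists of glycogen, imprinted and immediate early genes were chosen after the named genes had been seen, as were the genes picked from them; the limit of the cell type comparison to lists with at least 10 tested members and the repeats of the immediate early count under other settings were chosen after the results, as were the test of muscle genes by detection calls and the binomial limits. Ppp1r3b, which targets protein phosphatase to glycogen, had a signal of 1619 ± 43.4 in brown and 54.5 ± 11.9 in white (SD, n = 3; at least 30.2-fold), Gys2, the liver form of glycogen synthase, 506 ± 35.2 against 38.7 ± 22.0 (3.94; marginal on 1 white array and absent on the others), and Fbp2, the muscle form of fructose bisphosphatase, 362 ± 43.3 against 41.6 ± 9.70 (at least 8.80-fold). The liver form of glycogen phosphorylase, Pygl, was higher in brown (4899 ± 224 against 1252 ± 113), and the brain form, Pygb, was higher in white (590 ± 31.7 in brown against 1977 ± 155). The hypothesis that glycogen genes as a group are higher in brown was tested without Ppp1r3b, Gys2 and Fbp2: 10 of 19 were higher in brown and 4 in white (median 0.37; camera adjusted p = 0.0976 over the 3 added lists), which leaves it open.

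The imprinted genes Plagl1 and Nnat had log2 differences of -5.58 and -5.12, and Mest was at least 23.9-fold higher in white. The hypothesis that imprinted genes as a group are higher in white was tested without these and Dcn: 8 of 19 were higher in white, such as Grb10 (-1.63) and Peg3 (-1.14), 5 were higher in brown, such as Gnas (0.92), and 6 were not called (median -0.36; camera adjusted p = 0.622). It stays open. For these and the glycogen genes, an uncalled list had been written down beforehand as evidence against the hypothesis; that reading was given up after the results were seen, because a p above the threshold does not exclude a difference of the group.

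Of the genes Nr4a1, Nr4a2 and Nr4a3, which are induced rapidly in stimulated cells, the first 2 had log2 differences of 4.20 and 3.65 and Nr4a3 was at least 16.1-fold higher in brown. A general immediate early response of the brown samples, as handling could bring, predicts that most of the other immediate early genes are higher in brown. Of 21 such genes, 7 were higher in brown, such as Fos (1.40) and Egr1 (1.37), and 7 in white, such as Klf6 (-1.70) and Myc (at least 5.62-fold) (camera adjusted p = 0.849). Over 10 settings of scaling and arrays left out the number higher in brown ran from 4 to 9. In each setting this was under 1 in 2 of those tested, so the prediction was not met in any of them. Of all 10264 genes tested, 2895 were higher in brown and 3361 in white. With deposited and spike-in scaling 4 were higher in brown and 12 in white. The upper 95% binomial limit of 7 of 21 was 57.0%. This limit treats the genes as independent and does not measure the spread over arrays. Members went both ways. A general immediate early response, a response of a few of these genes and a difference between the tissues all stay open. A count of under 1 in 2 had been written down beforehand as evidence against the response. That reading was set aside after the results were seen, because 1 in 2 lies within the binomial limit.

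Markers of other cell types were mostly higher in white. A smaller share of adipocyte RNA in white would raise all of them alike. The medians of the endothelial list (-0.52, 95% bootstrap interval -0.94 to -0.34) and the macrophage list (-2.32, -2.63 to -1.92) lay 1.80 apart on the log2 scale. These intervals resample the genes of a list, not the arrays. With 1 array left out the medians ran from -0.648 to -0.515 and from -2.438 to -2.153. For these lists the gap argues against a smaller adipocyte share as the whole cause. The Schwann list lay on the other side at 0.83 (0.03 to 4.71). With 4 members, of which Sox10 and Egr2 were not called, it decides nothing. Epididymal epithelium carried over with white fat predicted at least 3 epididymis genes present on all white arrays, and 1 of 14, Rnase10, was, with Lcn2, Adam28 and Sult1e1 left out beforehand. Rnase10 was also present on 2 brown arrays and was not called (-0.25, limma adjusted p = 0.456). It was called higher in white with deposited (-0.72, limma adjusted p = 0.0422) and spike-in scaling (-0.73, 0.0438). With the sign-turned series table it was called higher in brown (0.33, 0.0496). Under 3 such genes had been written down beforehand as evidence against the carry-over. That reading was set aside because the upper 95% binomial limit of the number present was 4.74. This limit treats the genes as independent, and a small share stays open. Only 6 of 25 skeletal muscle genes passed the filter, and Ckm, Mylpf and Tnnt3 were not tested, so the count of calls planned for this test could not decide whether muscle was carried over with brown fat. By detection calls over all 25, tested or not, 3 were present on all brown arrays and 5 on all white arrays, these 3 among them. The upper 95% binomial limit of the share present in brown was 31.2%, below the share set as the prediction of carry-over. The mean deposited signal was higher in brown for 17 of the 25, such as Mylpf (44.9 against 3.6), and higher in white for others, such as Acta1 (66.9 against 217). Most of the 25, Mylpf included, were not present on all arrays of either tissue, so these directions cannot decide. Skeletal muscle carried over with the brown fat pad stays open. All 13 mesothelial genes, 9 of them absent on all brown arrays, and all 19 macrophage genes were higher in white, as a different cell composition would give. Composition was not measured, and how much of the differences it accounts for stays open.

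The 6 arrays make 10 splits into 3 and 3, which are too few for a share under 0.05, and for each count 1 of the 10 splits, the real one, gave a value as large. The real split gave 10809 probe sets, 4653 at least 2-fold, 6256 genes and 2009 probe sets detected in 1 tissue only, where the highest other split gave 0, 0, 0 and 53. For the camera lists the real split gave 16 of 27, and the other splits gave 12 to 15. Every other split put 2 arrays of one tissue with 1 of the other. The tissue difference then enters both the spread within groups and the contrast, so none of these values is a chance level. The number of lists called hardly set the real split apart.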
